A study of Nicotiana attenuata with 6 samples.

How the data were processed

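Stems of *Nicotiana attenuata*, a wild tobacco, were compared between wild-type plants and ir-CDPK4/5 plants, which carry an inverted-repeat transgene made to silence the calcium-dependent protein kinases CDPK4 and CDPK5. Each group had 3 samples from plants 41 days old, and each sample was hybridised to 1 Agilent array with a single dye, Cy3. The series' design text speaks of leaves for the wild type, whereas the labels of each of the 3 wild-type samples say stem, and the sample labels were followed. That text mentions 3 independent experiments for the ir-CDPK4/5 plants. Nothing states whether the wild-type samples came from separate plants, so the p-values measure the spread between these samples, which may be technical.

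The deposited scanner files hold linear spot intensity values. Spots were read with Agilent Feature Extraction 9.5 per the submitters' processing notes, and with version 9.1.1.1 per the file headers. Background subtraction, spatial detrending and surrogate values for dim spots were applied by that software per the file headers, and no scaling between arrays is recorded there. The authors' deposited value table holds log2 values. Its scale was worked out from the values, since no source used here states it: each column matched the log2 processed signal minus the 75th percentile of its array and minus the probe's median over the 6 arrays, with correlations from 0.99997 to 0.99998 across probes. The medians of its columns were -0.036, -0.0079 and -0.016 for wild-type replicates 1, 2 and 3, and 0.017, 0.058 and 0.020 for ir-CDPK4/5 replicates 1, 2 and 3. All 6 columns of the table belong to the 6 samples.

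Each array carried 43803 spots for 43533 probes, of which 30 were spotted 10 times. The array's own annotation gave 33639 probes an entry name of the protein database form, such as CDPK5_SOLTU, in which the last letters stand for a species, and 9894 probes a contig number and no protein. These 19036 distinct names mostly belong to proteins of other species, so a gene is called here by the name of the protein it was matched to, and several probes can carry the same name. None of these names matched the reference gene table, with 0 of its symbols found. No genome coordinates were used.

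The processed signal was put on the log2 scale, the 75th percentile of each array was subtracted, control spots and 175 spots with outlier flags were left out (150 of them on the array of ir-CDPK4/5 replicate 2), and spots of the same probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 28719 probes, 23503 of them with an entry name. Differences between the groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block) with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. In this design limma borrows information on the spread from other probes. Permutations of 3 against 3 arrays could not give a share under 0.1. Where a probe was not well above background on any array of a group, the fold is given as a lower bound: the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest value among probes well above background.

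The share of spots well above background was 64.5%, 71.7% and 69.5% on the arrays of wild-type replicates 1, 2 and 3, and 62.4%, 57.6% and 63.5% on those of ir-CDPK4/5 replicates 1, 2 and 3. At most 1 spot per array was saturated. The number of arrays, 3 per group, limits the precision of each value. In simulated data for ir-CDPK4/5 against wild type with 28616 probes, 50 probes each were changed by a log2 value of 0.5, 1, 2 and 3. Of these, 1, 19, 35 and 43 were recovered. Of 28386 unchanged probes 6 were called, and a shifted list was the 1 list called among 18. Noise was drawn independently for each probe. The simulation hence cannot show how often lists of correlated genes are called falsely, such as photosynthesis (estimated inter-gene correlation 0.52). A first, stricter criterion on the recovered share was not met. It was replaced by criteria on direction, bias, false calls and the shifted list after the gene list results had been seen.

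The comparison used 19 gene lists, each a pathway, a tissue marker set or a stress response, fixed as word patterns before the data were examined, as were the tests, the rule for naming genes and the alternatives. Because the files hold entry names and no product text, the patterns were translated into entry names after the files were opened and before group values were compared. The list of trichome markers had 0 probes on the array and was not tested. The other 18 were tested with limma's camera at the preset inter-gene correlation of 0.01, with 1 probe per name (the probe with the highest mean signal), and adjusted over the 18 lists. Probes with a left-out spot did not enter the list tests. Named genes were every probe named for CDPK4 or CDPK5, the 10 largest rises and the 10 largest falls among named probes past the threshold whose groups did not overlap, and from each list the 4 members with the lowest adjusted p (6 for the jasmonate biosynthesis, jasmonate signalling and gibberellin lists). The text gives part of them. After values had been seen, the mean used to choose the probe of a name was changed to the mean of both group means, so that a left-out spot no longer shifted it, which changed the probe that stands for ITR1_NICSY. THD1_SOLTU, PAL1_SOLLC, C94A2_VICSA, KSB_ARATH, RBS_TOBAC, LOX2_ARATH, STM_ARATH, RSH1_MAIZE, KNOS1_ORYSJ, KNAT7_ARATH, CDPK2_MAIZE, ICI1_CANLI, TIF8_ARATH, ACCO3_CUCME, PME55_ARATH and WRK64_ARATH were chosen after their values were seen.

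Alternatives were normexp background correction with an offset of 50, quantile normalisation, scaling to the median of the tested probes, no filter on dim probes, a filter that asked for all 6 arrays, the slide as a random and as a fixed block, the replicate number as a block, each array left out, limma's trended and robust prior, and the authors' value table. For the list tests an estimated inter-gene correlation and the use of every probe were added. Scaling to the ribosomal protein probes was chosen after seeing the data. The 6 arrays lay on 4 slides: wild-type replicate 3 shared a slide with ir-CDPK4/5 replicate 2, ir-CDPK4/5 replicates 1 and 3 shared another, and wild-type replicates 1 and 2 had a slide each. With the slide as a fixed block the estimate is the difference within the 1 slide that held both groups. Under the random block and the trended prior, list tests used the ranked form of camera on the model's statistics. A scan date block could not be fitted, since the arrays were scanned on 1 day.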

Results

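The data were 6 single-dye Agilent arrays of stem RNA from *Nicotiana attenuata* aged 41 days, 3 from wild-type plants and 3 from ir-CDPK4/5 plants, which carry an inverted-repeat transgene made to silence the calcium-dependent protein kinases CDPK4 and CDPK5. Values are log2 signals relative to the 75th percentile of the array, and log2 fold changes are ir-CDPK4/5 minus wild type. The 75th percentile of the signal was 264, 453 and 416 on the arrays of wild-type replicates 1, 2 and 3 and 209.8, 313 and 210.2 on those of ir-CDPK4/5 replicates 1, 2 and 3. Across tested probes, arrays within a group correlated with r from 0.976 to 0.992, and arrays of different groups with r from 0.807 to 0.842 (probes are not independent replicates). The comparison asked how the stem transcriptome differs between this line and wild type.

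Probes that carry the names CDPK4 or CDPK5, matched to proteins of other species, were examined first. The probe named CDPK4_ARATH (contig Na_454_13585) read 0.22, 0.12 and 0.12 in wild-type replicates 1, 2 and 3 and -0.48, 0.12 and -0.02 in ir-CDPK4/5 replicates 1, 2 and 3, a log2 fold change of -0.28 ± 0.18 (SE, n = 3 per group) that did not pass the threshold (limma adjusted p = 0.215). It was -0.0013 within the slide that held both groups, and passed at -0.79 after scaling to the ribosomal protein probes, which was chosen after seeing the data (limma adjusted p = 0.0331). Of 5 probes named CDPK5_SOLTU, 4 were tested and 2 were lower in ir-CDPK4/5. The brightest of them (Na_454_06727) read 2.15, 2.08 and 1.66 in wild type against 0.34, 0.77 and 0.22 in ir-CDPK4/5, a log2 fold change of -1.52 ± 0.21 (limma adjusted p = 9.08e-04). The second (Na_454_19844) changed by -0.84 ± 0.19 (limma adjusted p = 0.00922), and the other two CDPK5_SOLTU probes had log2 fold changes of -0.19 and -0.06 and did not pass. Within that shared slide the brightest CDPK5_SOLTU probe differed by -0.89 (limma adjusted p = 0.206). Of 9 tested probes named for CPK28 of *Arabidopsis* (CDPKS_ARATH), 1 was higher, by 1.85 (Na_454_05278), and 3 were lower. Over 43 tested probes named for any kinase of this family, 6 were higher and 9 lower. No probe carries the name of the *N. attenuata* genes themselves, and a probe inside the silencing fragment can bind transgene RNA, so these values check the sample labels weakly.

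**Figure D1:**
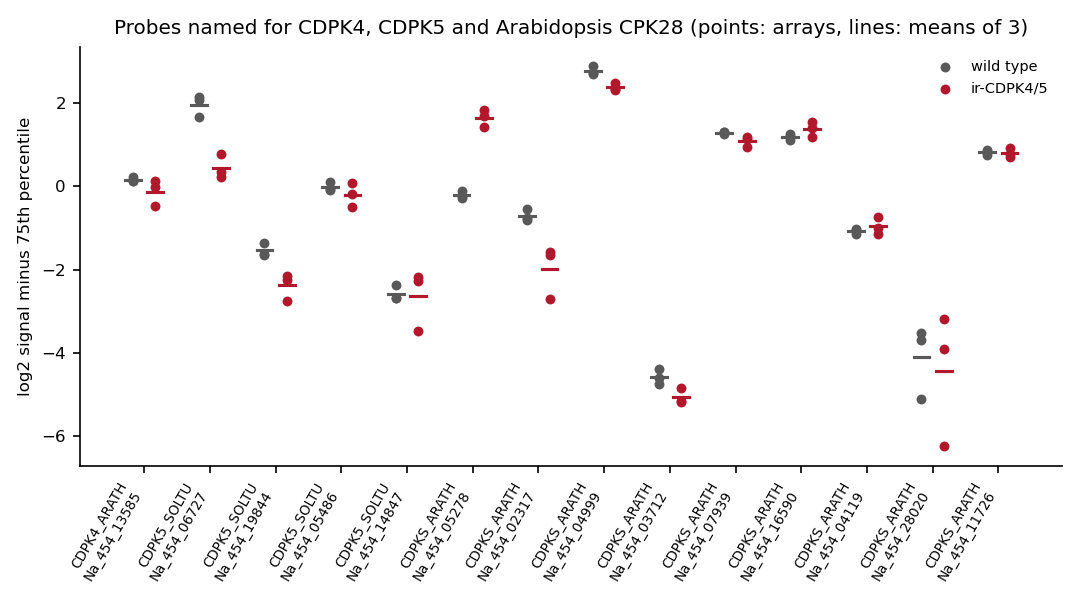
Log2 signal minus the array's 75th percentile (y axis) for the tested probes named CDPK4_ARATH, CDPK5_SOLTU and CDPKS_ARATH (x axis, with contig), in wild type (grey) and ir-CDPK4/5 (red). Points are arrays and lines are means of 3 arrays; CDPK5_SOLTU Na_454_06727 was lower by a log2 fold change of -1.52 and CDPKS_ARATH Na_454_05278 higher by 1.85.

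In ir-CDPK4/5 stems the list of jasmonate-induced antiherbivore proteins was higher than in wild type and the list of photosynthesis genes lower, with median log2 fold changes of 1.21 and -1.85. Neither list call held with an estimated correlation (camera adjusted p = 0.191 and 0.616), and pathogenesis-related proteins went both ways. Proteinase inhibitors and a polyphenol oxidase were among the 10 named genes with the largest rises, with a log2 fold change of 10.86 for the inhibitor ICI1_SOLLC. The inhibitor ITR1_NICSY was among the 10 with the largest falls. In all, 16347 of 28719 tested probes (56.9%) differed, 6336 of them higher and 10011 lower in ir-CDPK4/5, and 9008 differed at least 2-fold, 3629 higher and 5379 lower (limma). The share of higher calls was 38.8%, but it depended on the scaling: it was 52.5% after normexp background correction, 17.5% after scaling to the ribosomal protein probes (chosen after seeing the data) and 55.1% within the shared slide, and for calls of at least 2-fold it was 40.3% against 56.8%, 20% and 55.1%. The values of the groups did not overlap for 67.3% of the tested probes, where chance gives 10%.

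Among the 10 named genes with the largest rises, ICI1_SOLLC, ICID_SOLTU and PPOE_SOLLC are named for proteinase inhibitors or a polyphenol oxidase. ICI1_SOLLC and ICID_SOLTU, which are type I proteinase inhibitors, rose from means of -2.57 ± 1.32 and -2.41 ± 1.07 (SD, n = 3) to 8.29 ± 0.60 and 8.31 ± 0.47, log2 fold changes of 10.86 and 10.71 (limma adjusted p = 3.34e-05 and 1.72e-05). The polyphenol oxidase PPOE_SOLLC rose by 10.75, with 1 of 3 wild-type arrays well above background. PT2K4_SOLTU and PT2K3_SOLTU, named for patatins, rose by 10.81 and 10.48, with 2 of 3 wild-type arrays well above background for PT2K4_SOLTU. MECR_ARATH, named for a trans-2-enoyl-CoA reductase, had a log2 fold change of 13.52 ± 0.86, DCHS_RHILO, named for a histidine decarboxylase, 12.85 ± 1.16, and PUP2_ARATH, named for a purine permease, 11.45 ± 0.61, each with 1 of 3 wild-type arrays well above background. FL3H_HORVU, named for a flavanone 3-dioxygenase, was at least 1005-fold higher (limma adjusted p = 9.75e-06). CAHC_SPIOL, named for a chloroplast carbonic anhydrase, rose by 10.86 with 2 of 3 wild-type arrays well above background, against the direction of most photosynthesis genes. The other two probes of that name did not pass.

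The largest falls were more mixed. CYSEP_RICCO, a vignain-type cysteine endopeptidase, went from 7.81 ± 0.09 to -1.97 ± 0.90 (SD, n = 3), a log2 fold change of -9.77 (limma adjusted p = 1.09e-05), while the other two probes of that name rose by 1.82 and 1.24. ITR1_NICSY, a trypsin inhibitor of the serine proteinase inhibitor family, was at least 94.2-fold lower, and the other two probes of that name fell as well. ICI1_CANLI, named for a type I inhibitor, fell by 2.17. CET2_TOBAC, of the family of the flowering repressor CENTRORADIALIS, was at least 48.3-fold lower, LBD15_ARATH, a LOB domain protein, at least 21.1-fold lower, and SAM_RICPR at least 67.9-fold lower. GAO1A_WHEAT, a gibberellin 20-oxidase of gibberellin synthesis, had a log2 fold change of -5.63 ± 0.13 (limma adjusted p = 3.48e-06), with 2 of 3 ir-CDPK4/5 arrays well above background.

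**Figure D2:**
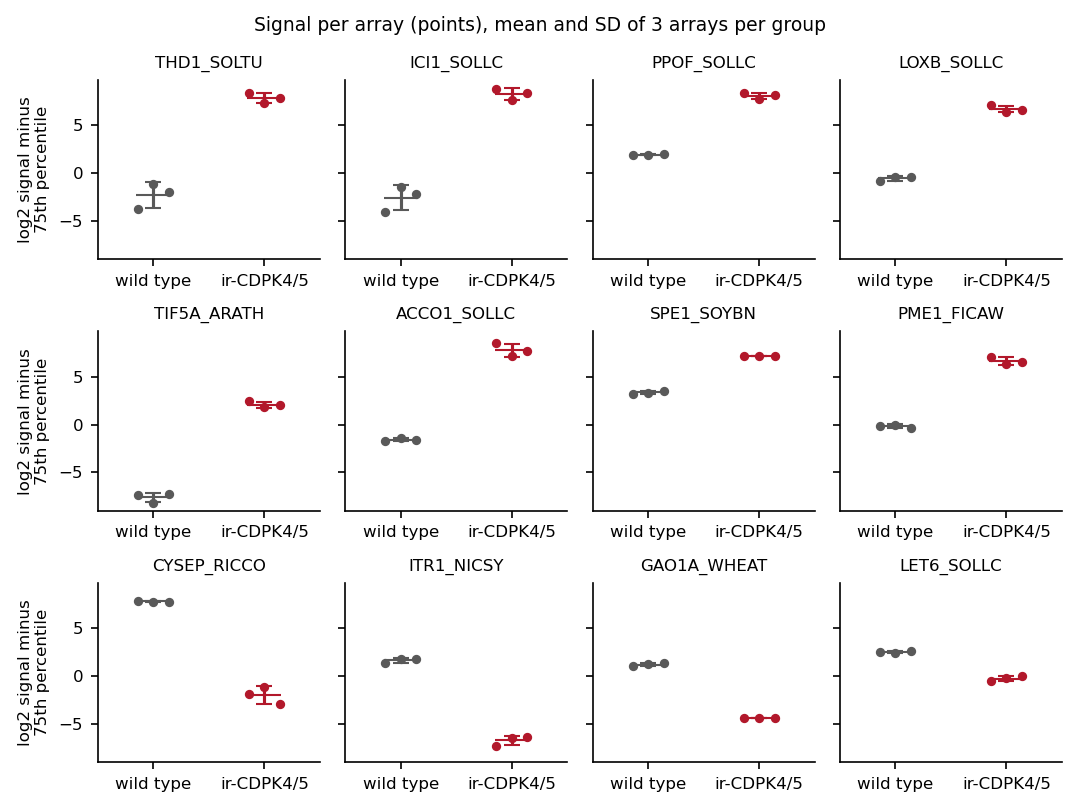
Log2 signal minus the array's 75th percentile (y axis) of 12 genes in wild type (grey) and ir-CDPK4/5 (red). Points are arrays, bars are means and SD of 3 arrays; TIF5A_ARATH in wild type and ITR1_NICSY in ir-CDPK4/5 were not well above background on any array, and CYSEP_RICCO fell from a mean of 7.81 to -1.97.

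Genes of the jasmonate pathway rose as a group, in samples where the median of the green-tissue list was -1.85. In jasmonate signalling and turnover, 19 of 27 tested probes were higher and 7 lower (19 and 7 adjusted over the list alone), with a median log2 fold change of 2.65 over 14 names (camera adjusted p = 1.89e-05, and adjusted p = 0.184 with an estimated correlation). The JAZ-type repressors, which jasmonate induces, were prominent: TIF5A_ARATH was at least 226-fold higher, TIF3B_ARATH rose by 4.18 ± 0.23 (SE), TI11A_ARATH by 3.80 ± 0.30 and TI11B_ARATH by 3.89 ± 0.32. TIF8_ARATH, of the same list, fell by 0.59. JMT_BRARP, a jasmonate methyltransferase, rose by 5.48. The probes named C94A2_VICSA, of the cytochrome P450 family that oxidises jasmonate conjugates, went both ways, from -5.73 to 5.11. In jasmonate biosynthesis, 22 of 30 probes were higher and 5 lower (22 and 5 adjusted over the list alone), with a median of 1.75 over 13 names (camera adjusted p = 0.00221, and adjusted p = 0.165 with an estimated correlation). AOC2_ARATH, an allene oxide cyclase, rose by 3.52 ± 0.14 and 4CLL5_ARATH by 1.87 ± 0.12. LOXB_SOLLC, which rose by 7.25 ± 0.22, and LOX1_ARATH, by 7.72 ± 0.38, are 9-lipoxygenases and do not make jasmonate precursors. LOX2_ARATH, a 13-lipoxygenase that does, fell by 1.28 and, at the second probe of that name, by 1.60, and of the other two LOXB_SOLLC probes 1 was lower and 1 did not pass.

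Jasmonate-induced antiherbivore proteins were higher on 23 of 38 tested probes and lower on 6 (23 and 6 adjusted over the list alone), with a median of 1.21 over 25 names (camera adjusted p = 5.47e-06, and adjusted p = 0.191 with an estimated correlation). THD1_SOLTU, a threonine deaminase that depletes threonine in the gut of herbivores, went from -2.30 ± 1.32 to 7.84 ± 0.51 (SD, n = 3), a log2 fold change of 10.14, while of the other two probes of that name 1 rose by 3.62 and 1 did not pass, at 0.32. PPOF_SOLLC rose by 6.16 ± 0.18 (SE) and IPIB_TOBAC, a proteinase inhibitor, was at least 56.6-fold higher. By name, 15 of 25 were higher and 2 lower. The lower names were the trypsin inhibitor ITR1_NICSY, at least 94.2-fold lower, and ICI1_CANLI, which fell by 2.17. In the phenolamide and phenylpropanoid pathway 19 of 21 probes were higher and 2 lower (19 and 2 adjusted over the list alone), with a median of 2.43 over 14 names (camera adjusted p = 4.35e-07, and adjusted p = 0.165 with an estimated correlation). SPE1_SOYBN, an arginine decarboxylase of polyamine synthesis, rose by 3.78 ± 0.13, TCMO_ZINEL, a cinnamate 4-hydroxylase, by 4.67 ± 0.26, and the phenylalanine ammonia-lyases PAL3_TOBAC and PAL1_SOLLC by 2.50 and 2.41. The nicotine biosynthesis list moved little, with 1 of 10 probes higher and 4 lower (1 and 3 adjusted over the list alone) and a camera adjusted p of 0.703. PMT4_TOBAC, a putrescine N-methyltransferase, fell by 0.92.

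Ethylene genes rose on 60 of 107 probes and fell on 15 (64 and 15 adjusted over the list alone), with a median of 0.96 over 61 names (camera adjusted p = 4.07e-08, and adjusted p = 0.0692 with an estimated correlation). ACCO1_SOLLC, an ACC oxidase of the last step of ethylene synthesis, rose by 9.34 ± 0.33 (SE), the ACC synthase 1A1C_SOYBN by 5.82 ± 0.19, and the ACC synthase 1A12_SOLLC was at least 74.7-fold higher, while ACCO3_CUCME fell by 1.52. Pathogenesis-related proteins were higher on 29 and lower on 35 of 100 probes (30 and 36 adjusted over the list alone). Their median was 0.31 over 44 names and -0.024 over probes, with camera adjusted p = 0.00572, adjusted p = 0.218 with an estimated correlation, and a median of -0.20 after scaling to the ribosomal protein probes. The call also ended after normexp (adjusted p = 0.105) and with every probe in the test (adjusted p = 0.317), with a range of 5.80e-04 to 0.317 over the alternatives. E132_SOLTU, a glucan endo-1,3-beta-glucosidase, was at least 181-fold higher, the defensin DEF2_PETHY rose by 6.63 and PRPX_HORVU fell by 2.63. Calcium signalling genes were higher on 49 and lower on 39 of 165 probes (49 and 39 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0352, and adjusted p = 0.165 with an estimated correlation) that was -0.36 after scaling to the ribosomal protein probes. That call also ended after normexp, quantile normalisation, either other filter, a random slide block or the trended prior, and without ir-CDPK4/5 replicate 2 (adjusted p = 0.0734), with a range of 0.0172 to 0.233 over the alternatives. The CBL-interacting kinases CIPKH_ARATH and CIPKB_ARATH rose by 4.62 and 3.90, while the other two CIPKB_ARATH probes did not pass. CIPK2_ORYSJ fell by 2.34, with 2 other probes of that name higher and 1 lower. Heat shock and tissue stress genes were higher on 37 and lower on 24 of 98 probes (37 and 26 adjusted over the list alone), with a median of 0.054 over 49 names and a camera adjusted p of 0.606, or 0.0137 with every probe in the test (range over the alternatives 0.0137 to 0.906). HSF24_SOLPE, a heat stress transcription factor, rose by 3.58 and HS17A_ARATH fell by 2.56, while the second probe of that name rose by 0.61.

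Growth-related lists moved less clearly. Gibberellin metabolism and signalling was higher on 10 and lower on 16 of 32 probes (10 and 18 adjusted over the list alone), with a median of -0.73 over 16 names, or -0.52 with genes not above background at their bounds (camera adjusted p = 0.332). Besides the fall of GAO1A_WHEAT, the 3-oxidase G3OX4_ARATH rose by 4.34 ± 0.31 (SE) with 1 of 3 wild-type arrays well above background. The gibberellin-inactivating 2-oxidase G2OX1_ARATH rose by 1.77 ± 0.21, with 2 other probes of that name higher and 1 lower. G2OX1_PEA fell by 3.98 ± 0.50, with 1 of 3 ir-CDPK4/5 arrays well above background. The ent-kaurene synthase name KSB_ARATH had a probe that fell by 1.84 and a probe at least 159.6-fold higher. Auxin response genes were lower on 113 of 195 probes and higher on 33 (117 and 33 adjusted over the list alone), with a median of -0.82 over 73 names (camera adjusted p = 0.0281, and adjusted p = 0.172 with an estimated correlation). This call ended without ir-CDPK4/5 replicate 1 (adjusted p = 0.0513), with the slide as a random block (adjusted p = 0.0577) and after scaling to the ribosomal protein probes (adjusted p = 0.245), with a range of 0.00101 to 0.245 over the alternatives. AIR12_ARATH fell by 2.79, with 1 other probe of that name higher and 2 lower. The auxin-conjugating GH39_ARATH rose by 2.51, with 2 other probes of that name higher and 1 lower.

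Cell wall loosening genes were higher on 62 and lower on 76 of 207 probes (64 and 76 adjusted over the list alone), with a median of -0.11, a mean of 0.35 and camera pointing up (adjusted p = 0.332). After scaling to the ribosomal protein probes camera passed, still pointing up (adjusted p = 0.0395, range over the alternatives 0.0395 to 0.729). The median was then -0.62. Pectinesterases went both ways, with 10 of 20 names higher and 6 lower, and did not pass as a family (camera adjusted p = 0.124, and adjusted p = 0.538 with an estimated correlation). PME1_FICAW rose by 6.82 and PME44_ARATH was at least 149.8-fold higher, while PME55_ARATH fell. The expansin EXP12_ORYSJ rose by 6.38. Lignin and secondary wall genes were higher on 40 and lower on 79 of 158 probes (40 and 79 adjusted over the list alone), with a median of -0.36, a mean of 0.032 and camera pointing down (adjusted p = 0.606), while the peroxidases PER2_ORYSI and PERA_IPOBA rose by 8.55 and 6.44. Cell division genes were higher on 16 and lower on 48 of 123 probes (16 and 47 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.332). The D-type cyclin CCD11_ARATH fell by 3.46 and CCD61_ARATH rose by 2.66. The linker histone H1_SOLPN fell by 1.83, while the second probe of that name rose by 1.39.

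Photosynthesis genes were lower on 88 of 104 probes and higher on 3 (91 and 3 adjusted over the list alone), with a median of -1.85 over 62 names (camera adjusted p = 8.89e-07, and adjusted p = 0.616 with an estimated correlation). CB121_HORVU, a light-harvesting protein, fell by 2.12 ± 0.17 (SE), PSBS_TOBAC by 1.62 ± 0.14 and the Rubisco small subunit RBS_TOBAC by 1.61 ± 0.35. Ribosomal protein genes were higher on 82 and lower on 5 of 193 probes (73 and 5 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 6.32e-06, and adjusted p = 0.724 with an estimated correlation) that was -0.014 after quantile normalisation, where the call ended, and -0.18 after scaling to the ribosomal protein probes. Vascular markers were higher on 9 and lower on 15 of 42 probes (10 and 15 adjusted over the list alone), with a median of -0.11, a mean of 0.28 and camera pointing up (adjusted p = 0.606). The phloem protein gene P2A15_ARATH rose by 3.68, while the second probe of that name fell by 0.59. Flower and meristem markers were higher on 14 and lower on 30 of 66 probes (14 and 30 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.227). The nectar protein gene NEC3_NICLS rose by 6.23 ± 0.21, and the meristem homeobox genes LET6_SOLLC and KN1_MAIZE fell by 2.79 and 2.64.

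**Figure D3:**
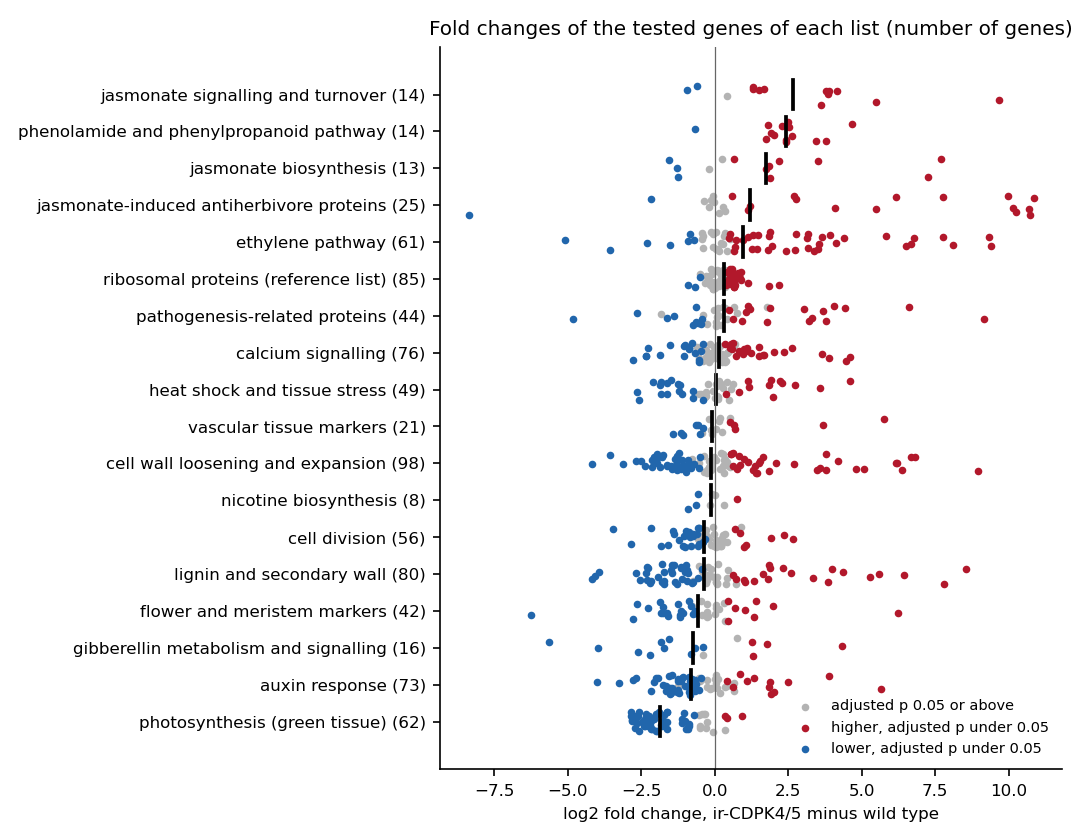
Log2 fold change, ir-CDPK4/5 minus wild type (x axis), of each tested gene of 18 lists (y axis, number of genes in brackets, 1 probe per name). Red and blue points passed the threshold as higher and lower, grey points did not, and black lines are medians, from 2.65 for jasmonate signalling and turnover to -1.85 for photosynthesis.

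Within the shared slide the list medians were 2.43 for jasmonate signalling, 1.75 for jasmonate biosynthesis, 1.14 for antiherbivore proteins, 2.35 for phenolamides, 0.80 for ethylene, -2.08 for photosynthesis and -0.85 for auxin. All 10 list calls were made at the preset correlation, and wrong splits of the 6 arrays called up to 8 lists. Each wrong split had arrays of both groups on both sides and kept part of the group difference. Its count is therefore not a rate of false calls. None held with an estimated correlation, whose p was the highest over the alternatives for the jasmonate, antiherbivore, phenolamide, ethylene, photosynthesis and ribosomal lists. The estimate itself was 0.0097 for ethylene, 0.0042 for auxin, -0.0050 for calcium signalling and -0.046 for jasmonate biosynthesis. These lie below the preset 0.01, so a higher correlation did not end those calls. For ethylene the unadjusted camera p went from 2.26e-09 to 0.00384 at nearly the same correlation. The estimated form of the test therefore differs in more than the correlation. For these lists, losing the call under it is no sign of correlated genes.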

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

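Scaling to the ribosomal protein probes was chosen after seeing the data. Scaling moved the median of the tested probes by -0.51 for ribosomal proteins and 0.12 for the tested probes' median. Against 9008 probes changed at least 2-fold, 4569 passed after normexp, and 5983 with all 6 arrays above background, where fewer probes were tested (23555). Within the shared slide, which sets 1 array against 1 and leaves 1 residual degree of freedom, 3288 probes and 3288 at 2-fold passed, CDPK5_SOLTU stood at -0.89 (adjusted p = 0.206, range over its alternatives 8.40e-05 to 0.206), and 16346 of 16347 called probes kept their direction (both arrays are also part of the group means). With each array left out, 13192 to 17034 probes passed, and 8625 to 9376 at 2-fold. CDPK4_ARATH reached -0.79 (adjusted p = 0.0331, the lowest over its alternatives, 0.0331 to 0.999) after ribosomal scaling. The estimated correlation left 0 lists, and CDPK5_SOLTU otherwise kept its call. Of 1561 values of 94 named genes under alternatives 1530 kept direction and call, 27 lost the call and 4 turned: after normexp, G3OX2_ARATH was 0.28, ARFG_ARATH 0.075, PSAK_HORVU 0.037 and PSBR_SPIOL 0.044, none well above background on any ir-CDPK4/5 array. Of 342 list values, 311 kept direction and call, 23 lost the call, 2 gained it and 6 turned direction in the test, none of them a called list: heat shock after normexp (median 0.065), vascular markers with no filter (-0.11), lignin with the random slide block (-0.36), the trended prior (-0.36) and ribosomal scaling (-0.87), and gibberellin after ribosomal scaling (-1.24); the cause was not tested. The replicate block gave 14308 probes, 9027 at 2-fold and 10 lists, with CDPK5_SOLTU at -1.52 and CDPK4_ARATH at -0.28. Deviations of arrays sharing a number correlated by 0.011, -0.17 and -0.16, and no array correlated best with its own number. Because deviations from a group's own mean constrain one another, these values cannot show whether the numbers pair the samples. The highest correlation of deviations, 0.26, was between wild-type replicate 3 and ir-CDPK4/5 replicate 2, which shared a slide. Probes near background are limited by signal over background.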

Other observations

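The tests of the slide, of an array with a wrong label, of green tissue in either group, of leaf in place of stem, of jasmonate signalling and of the probes named for the kinases, and the families of entry names, were chosen after the result was seen.

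Transcription factor names gave a further group. Of 38 families of entry names with at least 10 tested names, 2 passed: WRKY factors, with 18 of 31 names higher and 10 lower and a median log2 fold change of 1.92 (camera adjusted p = 0.00666, and adjusted p = 0.288 with an estimated correlation), and ethylene response factors, with 13 of 22 higher and 3 lower and a median of 0.81 (camera adjusted p = 0.00285, and adjusted p = 0.288 with an estimated correlation). The latter overlap the ethylene list. WRK64_ARATH rose by 4.89 (limma adjusted p = 1.66e-05). The laccases, with 8 of 11 names lower and a median of -1.72, did not pass (camera adjusted p = 0.0952).

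Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For 16347 changed probes and for 9008 changed at least 2-fold, 1 of the 10 splits, the real grouping, gave as many, and the highest other count was 0 for both. For the 10 lists, 1 split gave as many and the highest of the others called 8. The other splits had arrays of both groups on each side. They kept part of the group difference and put the rest into the residual spread, so neither count measures false calls.

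Of the tested probes, 56.9% differed. The slide was argued against, since the arrays of different groups on the shared slide correlated with r = 0.817, below the lowest value within a group, 0.976. That same 0.976 stood above the highest correlation between groups, 0.842, which argues against 1 array with a wrong label. Dimmer ir-CDPK4/5 arrays would leave bright probes unchanged, yet 24.5% of the 7180 brightest probes differed at least 2-fold. The photosynthesis median of -1.85 (SE 0.15) would be seen if wild-type stems held more green tissue, which stays open. The SE of a median over genes, here and below, comes from the spread between genes and treats them as independent. For photosynthesis the estimated inter-gene correlation was 0.52, so that SE may be too small. Leaf in place of stem in the wild type stays open too: the KNOTTED-like genes of the flower and meristem list, several of which stems express and simple leaves do not, had a median of -0.99 (SE 0.60) over 8 names. Of these, 5 passed as lower, which runs against leaf: LET6_SOLLC at -2.79, KN1_MAIZE at -2.64, RSH1_MAIZE at -1.26, KNOS1_ORYSJ at -1.16 and STM_ARATH at -0.82, while KNAT7_ARATH rose by 1.40. The genes, and the bound of 2 SE that left this undecided, were chosen after their values had been seen.

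For the antiherbivore genes, floral tissue in the ir-CDPK4/5 stems stayed undecided: the flower and meristem list had a median of -0.55 (SE 0.34), but it mixes meristem with floral genes, its members went both ways and NEC3_NICLS rose by 6.23. General stress at harvest stayed undecided too: the heat shock and tissue stress list had a median of 0.054 (SE 0.27) over members that went both ways (camera adjusted p = 0.606), and passed upward with every probe in the test (adjusted p = 0.0137). Both lists met the criterion written before the result, a median below 1 by more than its SE, which would count against both explanations. The explanations were left undecided under a bound chosen after the values had been seen, a median within 2 SE of 0. A lower share of green tissue was tested as if it raised all other transcripts by about 1 factor. Of the antiherbivore list 40% was at least 16-fold higher, against 2.12% of the 14456 other tested entry names outside the photosynthesis list (Fisher's exact p = 5.20e-11, two-sided). This comparison set was chosen after values had been seen. The p treats genes as independent, although the list's estimated inter-gene correlation was 0.17. These shares run against a uniform rise only. Another tissue in place of green tissue, with high expression of these genes, stays open. Higher jasmonate signalling may account for part of the rise, since the signalling list had a median of 2.65 (SE 0.92), but its members and the antiherbivore genes were measured in the same 6 arrays. It would not account for ITR1_NICSY of the antiherbivore list, which was at least 94.2-fold lower. The age, position and developmental stage of the stems within the plants were not tested.

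Of the 5 tested probes named for CDPK4 or CDPK5, 2 were lower. A probe named CDPK2_MAIZE fell by 1.46 while another of that name rose by 2.02, against a fall of 1.52 for the CDPK5_SOLTU probe that fell most (SE of the difference 0.30), so it cannot be told apart from these values whether the probes named for CDPK4 and CDPK5 measure other kinases. Among probes named for CDPK4, CDPK5 or CPK28 that passed, 1 was higher and 5 were lower, which leaves an exchange of the labels of both groups undecided.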
